A study of Mus musculus with 2 samples.

How the data were processed

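The data were 5C (chromosome conformation capture carbon copy) matrices from resting B cells of the spleen of C57BL/6 mice, left unstimulated. In 5C, chromatin is fixed with formaldehyde, cut with a restriction enzyme (here HindIII) and ligated, and the ligation products of chosen fragments are amplified with forward and reverse primers and sequenced. A read count for a forward and a reverse primer then measures how often their 2 fragments were joined. Cells were isolated as CD43-negative cells with magnetic beads, per the labels' protocols. There was 1 group of 2 libraries, which the design text describes as biological replicates, so the design holds no contrast between conditions. Its criterion for a looping interaction is detection in both replicates, and the comparisons made here are those between pairs of fragments, between parts of the locus and between the replicates.

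The deposited values are counts of sequenced ligation products per primer pair, with forward primers in rows and reverse primers in columns, as all-by-all matrices from the my5C web tool, per the file headers. The headers name a step called transpurge, and the submitters' processing notes name Novoalign and the genome build mm9. Versions, mapping settings and the meaning of the remaining file name suffixes are not given in the sources used here. All values were whole numbers, both libraries had different totals, and summed counts per primer ran from 2569 to 2314265 in replicate 1 and from 2040 to 2559130 in replicate 2. No correction for the coverage of single fragments was visible in these values, but without the meaning of the suffixes it is not known whether one was made, and differences between primers in recovery, ligation and amplification may remain in them. Wide differences between primers also come from pairs that share a site and from contacts. Reads carried no stated molecular identifiers, so intervals and limits from counts cover counting error only.

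The matrices held 98 forward and 108 reverse fragments of chromosome 12, of the 112 and 113 primers in the design text, which gave 10584 primer pairs. The design also tiled a gene desert on chromosome 5 with 24 forward and 25 reverse primers. Those pairs were not analysed here, so the planned comparisons with the desert were not made. Fragments are named here by primer type and number (F31, R33) and by mm9 coordinates, counted from 1 as in the files. The RefSeq gene table at hand was of assembly GRCm38, a different build, so it was used only for gene names and their order, and no fragment was assigned to a gene.

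For each library, the expected count at each distance between fragment midpoints was taken from a LOWESS fit of the count on log10 distance over all pairs, zeros included (span 0.2, no robustness steps). The residual was divided by the square root of the LOWESS-smoothed squared residual to give z. A pair was called when z was 2 or more in both libraries. The number called was compared with the number after permuting the pairs of replicate 2 within 10 distance bins of equal count (10000 draws, one-sided). Called pairs per fragment were tested by permuting pair labels within the same bins (10000 draws, one-sided), with Benjamini-Hochberg adjustment over the 206 fragments, each with at least 10 assayed pairs. The assayed interval was divided into 5 segments of equal length, and the mean z of the 15 segment pairs was tested against all 206 cyclic shifts of the segment labels along the fragment order (two-sided). Insulation was the mean z of pairs that span a gap with both fragments within 250 kb of it, for at least 10 pairs. A local minimum was the lowest of the 5 gaps on each side, and minima within 1 fragment of each other in the 2 libraries counted as shared. The decay slope was fitted to log10 mean count against log10 distance in 20 bins.

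A second quantity, called fragment-corrected z here, was added after the data were examined. It is z of log2(count + 1), with a pseudocount of 1, after removal of the additive effects of each forward and reverse primer. The alternatives fixed before the data were examined were other z thresholds, LOWESS spans, segment numbers and windows, the log2 scale, iterative correction over primers (100 rounds), filters on low counts, low fragments and pairs under 50 kb, thinning of replicate 1 to the depth of replicate 2, and leaving out each replicate. The named items were fixed at the same time as the 25 called pairs with the highest mean z, the 10 fragments with the most called pairs among those past the test (ties by mean z), and the 5 deepest shared insulation minima. The 3 further fragments past the test are named too, and were chosen after their values were seen.

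The functions were tested on simulated counts for all 10584 pairs. These followed the mean decay of each library with independent noise (squared coefficient of variation 0.5) and no primer or fragment effects. The rates below therefore need not hold for the real counts, and a fragment raised by primer efficiency alone would also pass the fragment test. Of 100 pairs raised 10 times, 18% were called, and of 100 pairs raised 30 times, 73%. With no pair raised, 21 pairs were called, so a call alone does not show that a pair is raised. In the fragment test, 5 of 5 fragments raised 8 times were recovered, and 0 unchanged fragments passed. A segment pair raised 2 times reached the smallest p that the shifts can give, 0.00485, but its adjusted p was 0.0728. A simulated boundary was found at its own gap. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

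Replicate 1 held 16067416 counts and replicate 2 held 15096402. A count of 0 allows up to 3 counts, or 1.87e-05% of replicate 1 and 1.99e-05% of replicate 2.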

Results

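Chromatin contacts across the immunoglobulin heavy chain (Igh) locus were measured by 5C in unstimulated resting splenic B cells of C57BL/6 mice, to map the interactions of the whole locus. The 2 libraries form 1 group. The assayed fragments ran from 114339456 to 117350186 on chromosome 12 (mm9), an interval of 3.01 Mb. In the RefSeq table of assembly GRCm38, gene segments of the locus run, from low to high coordinates, from the constant-region genes (Igha, Ighe, Ighg2c, Ighg2b, Ighg1, Ighg3, Ighd and Ighm, which encode the antibody classes) through 4 JH segments and 10 DH segments with 10 DH pseudogenes to 120 VH segments and 63 VH pseudogenes. The low-coordinate end of the interval is therefore the constant-region end, and the high-coordinate end is the distal VH end. Replicate 1 held 16067416 counts over 10584 primer pairs, with 156 pairs at 0, and replicate 2 held 15096402 counts, with 223 pairs at 0. The median count per pair, averaged over the libraries, was 100 ± 7.07 (SD, n = 2).

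Most ligation products joined fragments that lie close together. Pairs under 100 kb apart held 85.8% ± 0.0402 (SD, n = 2) of all counts, pairs from 100 kb to 1 Mb held 9.21% ± 0.211, and pairs over 1 Mb apart held 5.01% ± 0.171. The 81 pairs whose fragments share a HindIII site, and so are neighbours in the genome, alone held 60.43% of replicate 1 (95% Wilson interval 60.40% to 60.45%) and 61.93% of replicate 2 (61.91% to 61.96%). Products of uncut or re-joined chromatin cannot be separated from contacts in such pairs. The 10 pairs with the highest counts held 39.7% of replicate 1 and 41.9% of replicate 2. Without the pairs that share a site, the share over 1 Mb was 12.9% ± 0.793.

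Counts fell steeply with distance up to about 1 Mb and then levelled off. In replicate 1 the mean count per pair was 24918 at 14.4 kb, 471 at 230 kb, 140 at 917 kb and 114 at 1.49 Mb. In replicate 2 the means at these distances were 23517, 425, 133 and 110. The log-log slope over all distances was -0.86 ± 0.0165 (SD, n = 2). At the longest distances, where only fragments from opposite ends of the locus can pair, the mean count was higher again, at 206 in replicate 1 and 217 in replicate 2 at 2.79 Mb. The median count moved the same way, from 54 at 1.49 Mb to 122 at 2.79 Mb in replicate 1 and from 52 to 120 in replicate 2. After iterative correction over primers this order was turned, with corrected means of 400 at 1.49 Mb and 290 at 2.79 Mb in replicate 1, and of 441 and 290 in replicate 2. That correction kept the pairs that share a HindIII site, which held most counts. Whether the turn comes from them or from primer effects cannot be told. No test across the 2 libraries was made, so these values are descriptive.

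**Figure D1:**
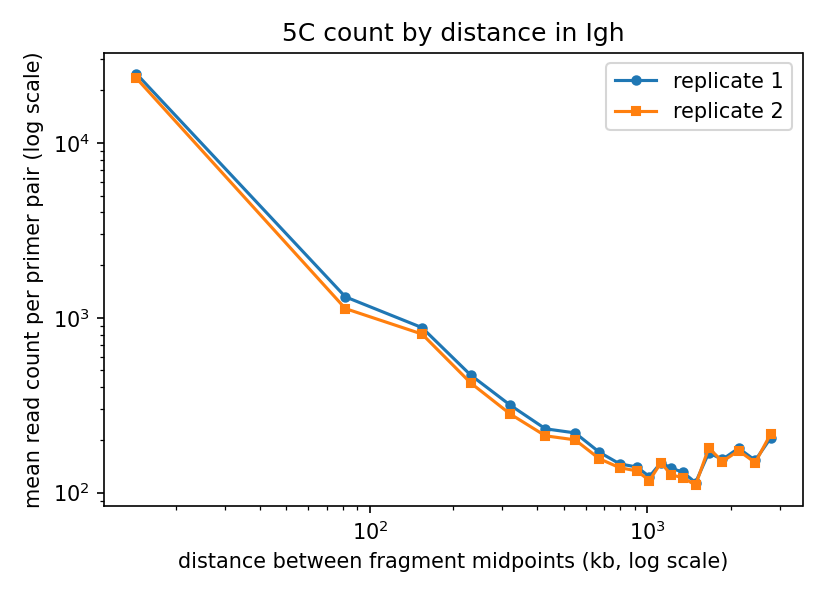
Mean read count per primer pair (y axis, log scale) against the distance between fragment midpoints (x axis, kb, log scale) in 20 distance bins of equal size, with a line for each replicate. Both lines fall until about 1 Mb and lie higher at 2.79 Mb (206 and 217) than at 1.49 Mb (114 and 110).

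The replicates ranked the pairs alike. Across pairs, which are not independent replicates, Spearman's rho between replicates was 0.92 for counts and 0.87 for z, after distance was taken out, and Pearson's r was 0.996 and 0.943. The highest rho for z among 10000 permutations within distance bins was 0.0733 (one-sided permutation p = 0.0001, the smallest that they can give). Agreement was lower for what is specific to a pair: for fragment-corrected z, rho was 0.60 and r was 0.59. The libraries were not copies of each other, since their counts differed by 30.1 times the chi-square expected from sampling (10519 degrees of freedom). Among the 4635 pairs with at least 100 counts in both libraries, the median fold difference between libraries was 1.26.

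Detection in both replicates picked out 153 of 10584 pairs (1.45%), where permuted replicates shared 5.25 on average and 16 at most (one-sided permutation p = 0.0001, the smallest possible). Permuting single pairs also breaks up primer and fragment effects that both libraries share. This p therefore shows that high values were repeated, and cannot tell contacts from such effects. Replicate 1 had 224 pairs with z of 2 or more and replicate 2 had 199. Of 907 assayed pairs under 100 kb apart 10 were called (1.10%), of 4546 between 100 kb and 1 Mb 88 (1.94%), and of 5131 over 1 Mb 55 (1.07%). The median distance was 826 kb for called and 967 kb for all assayed pairs, and the longest of a called pair was 2.99 Mb. Since z is scaled at each distance, calls at all distances follow in part from the method. Each called pair had at least 495 counts in each library. Of the called pairs, 112 (73.2%) had at least 1 fragment in segment 1 of 5 (114339456 to 114941602), at the constant-region end. This segment holds 72 of the 206 fragments and takes part in 57.8% of all assayed pairs. The difference between these shares was not tested, and which gene segments lie in segment 1 was not determined. Segment 5 (116748041 to 117350186) took part in 15.0% of called and 30.3% of assayed pairs. On the log2 scale 71 pairs were called, 64 of them among the 153. With additive fragment effects removed 18 were called, 11 of them among the 153, against at most 2 in permuted replicates. After iterative correction 145 were called, 26 of them among the 153. In simulated counts with no raised pair and no primer or fragment effects, 21 pairs met the z threshold of 2 in both libraries.

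Among the 25 interactions with the highest z, counts were between 9.58 and 132 times those expected at their distance in each library, 10 were over 1 Mb apart and 19 had an end in segment 1. The highest joined fragment F517 (116222484 to 116231679) with R41 (114528706 to 114531105), 1.70 Mb apart, with 13829 and 20537 counts in replicates 1 and 2, which is 111 ± 29.6 times the expected count (SD, n = 2). F165 (114973711 to 114977500) and R819 (117289594 to 117292548) lay 2.32 Mb apart and had 97.5 ± 2.45 times the expected count. Other pairs spanned nearly the whole locus. F842 (117325410 to 117328516) and R83 (114667887 to 114670119), 2.66 Mb apart, had 34.1 ± 9.94 times the expected count. F18 (114404465 to 114408145) and R831 (117305833 to 117307899), 2.90 Mb apart, had 25.7 ± 6.37 times. These 4 pairs were also called with additive fragment effects removed. After iterative correction F517-R41 and F165-R819 were still called, while F842-R83 fell to a mean z of 0.63 and F18-R831 to 1.92 and lost their calls.

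Several of the shorter interactions also stood far above their distance. F685 and R606 in the distal part of the locus, 270 kb apart, had 54.1 ± 4.30 times the expected count, and F513 and R403, 425 kb apart, had 40.3 ± 13.1 times. F792 and R768, 91.2 kb apart near the distal VH end, had 59.4 ± 4.02 times. F28 and R24 at the constant-region end, 21.5 kb apart, had 37.5 ± 1.90 times, with 374831 and 315936 counts. These 4 pairs too were called with additive fragment effects removed, which makes 8 of the 25. F513-R403 lost its call after iterative correction, with a mean z of 2.09 but not 2 or more in both libraries, and the other 3 kept it. F115 and R70, both in segment 1 and 134 kb apart, had 76.8 ± 5.99 times the expected count, with fragment-corrected z of 1.95 and 1.77.

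The other 16 interactions mostly shared few fragments. R33 was an end of F158-R33, F233-R33, F346-R33 and F272-R33, which had 18.7, 13.7, 14.8 and 10.6 times the expected count. R83 was an end of F233-R83, F272-R83 and F415-R83, with 16.3, 13.7 and 16.4 times. R81 was an end of F415-R81, with 52.9 ± 0.747 times at 1.15 Mb, of F346-R81, with 13.4 times, and of F82-R81, whose fragments share a HindIII site and had 16.3 times. The remaining pairs were F34-R181 (25.0 times), F16-R208 (14.6 times), F40-R274 (11.9 times), F837-R435 (15.9 times), F850-R499 (14.7 times) and F329-R41 (13.4 times). None of these 16 pairs had a fragment-corrected z of 2 or more in both libraries. After iterative correction F34-R181, F16-R208, F40-R274 and F329-R41 were still called and the other 12 were not.

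**Figure D2:**
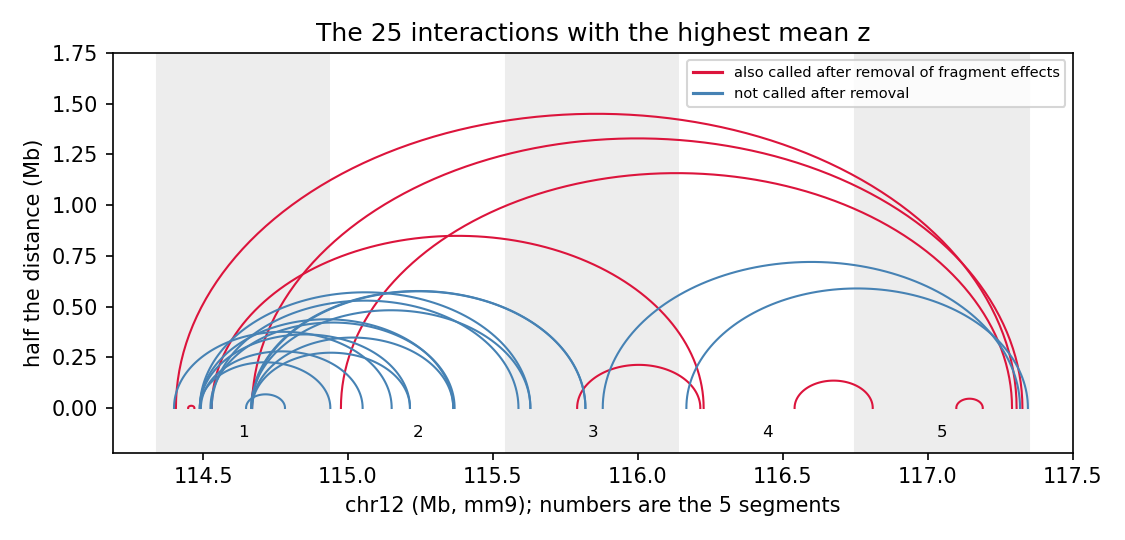
Arcs join the fragment midpoints of the 25 interactions with the highest mean z along chromosome 12 (x axis, Mb, mm9), with a height of 0.5 of their distance (y axis, Mb) and the 5 segments shaded and numbered. The 8 red arcs were also called with additive fragment effects removed, and 4 of them span more than 1 Mb.

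Reproducible interactions were concentrated on few fragments. Of 206 fragments, 13 had more called pairs than permuted pairs at the same distances gave (adjusted permutation p under the threshold of 0.05), 22 had an unadjusted p below that value, and 113 had no called pair. The 13 fragments took part in 110 of the 153 called pairs (71.9%), and 23 of the 42 pairs that join 2 of them were called. Both shares are high in part by selection, since the 13 were picked for their many called pairs. In segment 1, R33 (114486613 to 114491122) had 21 called pairs against 1.26 in permutations (adjusted permutation p = 0.00294). Its partners were 9 fragments of segment 1, 3 of segment 2, 6 of segment 3 and 3 of segment 4, up to 2.15 Mb away. F31 (114477117 to 114480873), close by, had 17 called pairs, and R81 (114664824 to 114667095) had 16, with partners in all 5 segments. R44 (114539129 to 114547720) had 9 and F38 (114502800 to 114510164) had 7.

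In the rest of the locus, R435 (115877939 to 115880010) had 11 called pairs, F611 (116559256 to 116561326) had 10 and F556 (116385510 to 116386658) had 9. F233 (115211655 to 115215965) and F415 (115816276 to 115822016) had 7 each, of which 5 in each case joined segment 1. The 3 further fragments past the test were R235 with 7 called pairs, R83 with 6 and R499 with 6. Iterative correction over primers ended all of these calls: 6 fragments passed then, and 0 of them were among the 13. That correction included the pairs that share a HindIII site, and none without them was run. On the log2 scale 6 passed, 5 of them among the 13.

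**Figure D3:**
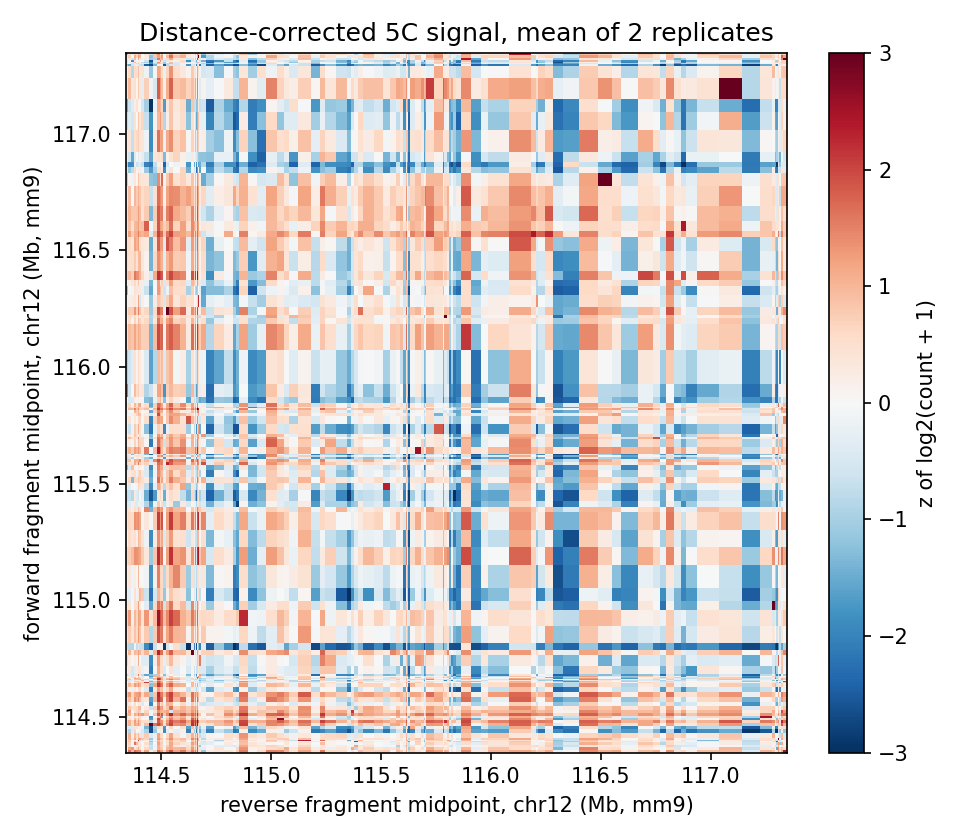
Distance-corrected signal (colour, z of log2(count + 1), mean of 2 replicates) for each forward fragment (y axis) and reverse fragment (x axis) by midpoint on chromosome 12 (Mb, mm9). Signal runs in whole rows and columns, so that it follows single fragments over all their partners.

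**Figure D4:**
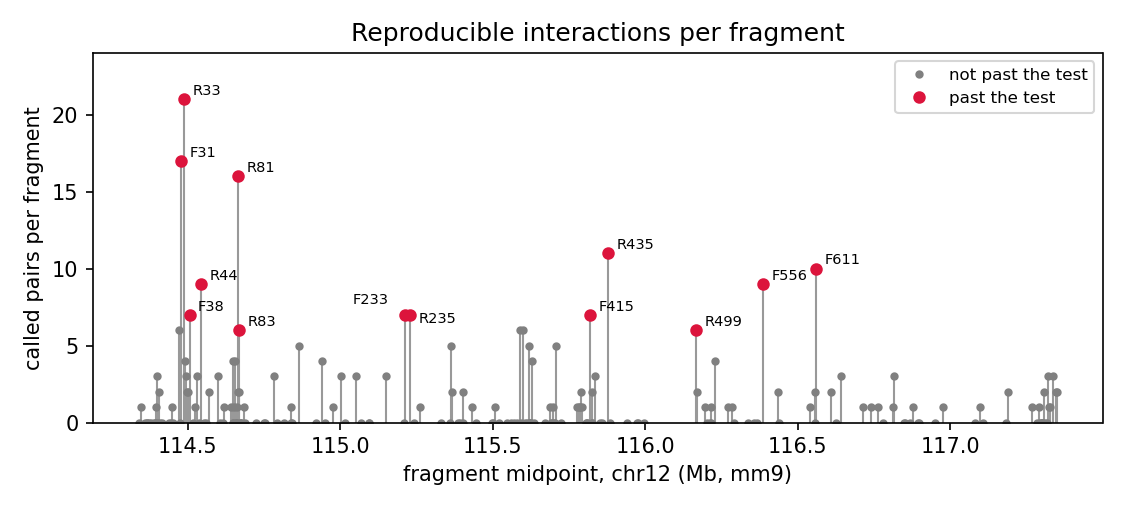
Number of called pairs (y axis) of each of 206 fragments by midpoint on chromosome 12 (x axis, Mb, mm9), with the 13 fragments past the permutation test in red. R33, F31 and R81, with 21, 17 and 16 called pairs, lie in segment 1, at the low-coordinate end.

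No pair of the 5 segments passed the test of its mean contact level at its distance. The mean z of the 15 segment pairs ran from -0.20 within segment 3 (115543749 to 116145894) to 0.14 between segments 1 and 4, and 0 of 15 passed the two-sided test over all 206 cyclic shifts (smallest adjusted permutation p = 0.811, with 0 below an unadjusted p of 0.05). Both libraries gave nearly the same values, with -0.20 and -0.20 within segment 3 and 0.15 and 0.12 between segments 1 and 4. The share of called pairs was 2.16% within segment 1, 2.78% between segments 1 and 2, 2.11% between 1 and 3, 1.39% between 1 and 4 and 0.654% between 1 and 5. It was highest within segment 4, at 2.98% (5 of 168 pairs), and 2.33% between segments 3 and 4. It was 0 of 525 pairs within segment 3 and 0 of 187 within segment 2. A single segment pair cannot pass this test, because the smallest p of 0.00485 becomes 0.0728 after adjustment over 15.

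Insulation, the mean z of contacts across a gap, had 6 local minima shared by both libraries, of 10 in replicate 1 and 8 in replicate 2. The deepest lay between 117081675 and 117095670 in the distal VH part, with a mean z of -0.32 ± 0.0253 (SD, n = 2) over 86 pairs. The next lay between 115885590 and 115938466, with -0.25 ± 0.00442, and between 115243663 and 115259493, with -0.22 ± 0.0128. The next minimum, at 116556522, had -0.02 ± 0.0281, and the last named, at 114672758 in replicate 1 and 114670119 in replicate 2, had 0.04 ± 0.00812. These 2 lay above the median of all 148 gaps, -0.15, and were dips only against their surroundings. Of the 6 minima, 3 were found again after iterative correction, 4 on the log2 scale and 2 with additive fragment effects removed, where the deepest had -0.029 and was no longer a minimum. Of the 5 named, 3 had a value with a window of 500 kb and 0 of these were found again, and 4 had a value with 150 kb and 2 of these were.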

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

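The removal of fragment effects on the log2 scale, the omission of pairs that share a HindIII site, the log2 scale for fragments and minima, and the log-mean slope were chosen after seeing the data. The count of 153 called pairs was 242 at a z threshold of 1.5, 69 at 3, 71 on the log2 scale and 18 with additive fragment effects removed. Single replicates gave 199 to 224. It stayed within 1.5 times under the other 8 alternatives (115 to 229), although only 26 of the 145 pairs called after iterative correction were among the 153. The Spearman correlation of z between replicates stayed between 0.60 and 0.90 and past its permutation test. The decay slope of -0.86 was -0.99 with 10 bins, -0.57 without pairs under 50 kb, -0.73 without pairs that share a site, -0.64 from mean log10 counts, and -0.87 to -0.85 in single replicates. The 13 fragments with excess calls were 8 at a z threshold of 3 (7 among the 13), 6 after iterative correction and 6 on the log2 scale, and 15 to 17 in single replicates, where F233 lost its call without replicate 2 (adjusted permutation p = 0.0855). Shared minima numbered 11 with a 150 kb window, and single replicates had 8 to 10. After iterative correction 59.3% of the signal lay under 100 kb, 27.2% between 100 kb and 1 Mb and 13.5% beyond. Without pairs that share a site these were 63.4%, 23.7% and 12.9%. In single replicates they were 85.8% to 85.8%, 9.07% to 9.36% and 4.89% to 5.13%. The cyclic-shift test called 0 segment pairs in all 7 alternatives, with at most 2 at an unadjusted permutation p under 0.05.

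Iterative correction left 10 of the 25 named pairs called, ended the call of 7 at a positive mean z (such as F415-R81 at 0.095 and F842-R83 at 0.63) and turned the sign of 8: F158-R33 (-0.057), F346-R81 (-0.62), F233-R83 (-0.054), F272-R83 (-0.56), F415-R83 (-0.14), F837-R435 (-0.077), F346-R33 (-0.49) and F272-R33 (-0.51). It left R33, R44, R81 and F233 with 0 called pairs and F415 with 1, below their permuted means. It moved the deepest minimum from -0.32 to -0.14 and the last named one to -0.028, and the log2 scale moved the last to -0.0070. These corrections remove any effect of a whole fragment by construction, so they cannot tell primer efficiency from contacts of that fragment with all others. Iterative correction also kept the 81 pairs that share a HindIII site, which weigh heavily in the sums that it evens out. In replicate 1, F82-R81 alone held 1510088 of the 2314265 counts of R81. No iterative correction without these pairs was run, so their part in the lost calls is not known. The gene desert results, and the alternative that takes the expected count from the desert, were not run. No paired analysis was possible because the design has 1 group, so no groups share replicate numbers. Thinning replicate 1 to the depth of replicate 2 gave 152 calls, but it removed few counts (16067416 to 15095248) and so says little on depth. Depth limits the 64 pairs at 0 in both libraries.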

Other observations

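The tests of the 25 named pairs alone, of the 18 pairs called with additive fragment effects removed, of hubs as neighbours of each other, of hubs by segment, of runs of raised fragments, of counting noise and of bins with limited values were chosen only after the result was seen. With additive fragment effects removed, contacts between regions of 150 kb were tested too, with another value and another permutation than the 5 segments had. Of 190 pairs of bins with at least 10 assayed pairs, 41 had a mean fragment-corrected z past a two-sided permutation test with Benjamini-Hochberg adjustment and the same sign in both libraries. Of these, 17 had a mean above 0 and 24 below 0. The bin from 114789456 to 114939455 stood out. Its mean z was 0.38 with the bin from 114339456 to 114489455 at the constant-region end (96 pairs, adjusted permutation p = 0.00292), 0.33 with the next bin (69 pairs) and 0.19 with the bin adjoining it on the low side (93 pairs). With the 15 tested bins farther toward the distal VH end it was below 0, and 7 of these passed, with -0.35 for 116289456 to 116439455 (29 pairs), -0.51 for 117039456 to 117189455 (16 pairs) and -0.28 for 117189456 to 117339455 (64 pairs) as the lowest. The other 8 did not pass, among them the bins 116439456 to 116589455 (-0.024) and 116589456 to 116739455 (-0.034). Permuted pairs at the same distances did not centre on 0 everywhere, since the value of -0.034 had an unadjusted permutation p of 0.9875. A mean z below 0 need not therefore be low for its distance. All these values rest on the same few fragments of the bin that stood out (F117, R125, R129, F130, R131, R137, R153 and F158). Their summed counts in replicate 1 ran from 3053 (F117) to 69476 (R137).

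In the distal part, the bins 116289456 to 116439455 and 116739456 to 116889455 had the highest mean z, 0.56 (29 pairs, with 0.56 in each library), and 0.47 without their highest pair. The bin at the constant-region end also had a mean z of 0.28 with 115839456 to 115989455, 1500 kb away (84 pairs, 0.22 and 0.33 in the 2 libraries). Across bin pairs, r between libraries was 0.89. All 41 kept their sign without the pair farthest out, and with single z values limited to 2 in size 39 of the 41 passed. Whether these regions prefer or avoid each other beyond distance stays open, since the 41 bin pairs are the pattern itself and no separate test of it. Removal of fragment effects makes each fragment's values sum to 0, so a raised bin must be matched by lowered ones, and permuted pairs are treated as independent, which pairs that share a fragment are not.

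The fragments with many reproducible interactions, such as R33, F31 and R81, may owe them to the efficiency of single primers or fragments, while a chromatin region with raised contacts would raise its other fragments, with primers of their own, too. The 21 nearest other fragments, at a median of 4.68 kb, had a mean effect of -0.084 (log2-scale z, SD 0.60) against 0.90 (SD 0.35) for the 13 fragments (one-sided permutation p = 0.7364, and 0.2989 with hubs counted as each other's neighbours). In segments 2 to 5 the 12 neighbours had -0.27 (SD 0.67) against 0.69 (SD 0.26) for the 7 hubs (permutation p = 0.9317). Except in the test with hubs counted as neighbours, the neighbours held no hubs while the random sets could, which raises p. In segments 2 to 5 only 3 of the 12 neighbours lay above 0, so these values gave no sign there of raised contacts that span many other fragments. They cannot exclude such contacts, since the effect of each neighbour also holds the efficiency of its own primer. Some neighbours also lay far off, such as R464 (ending at 116000828) beside R499 (starting at 116166285). The values leave open fragment efficiency and a region of adjacent hubs, such as F233 and R235. In segment 1 the 9 neighbours had 0.16 (SD 0.41; permutation p = 0.1975), but 13 fragments that follow each other when hubs are left out, F34 to R55 (114491123 to 114612029, with the hubs F38 and R44 among them), had a mean effect of 0.53 (SD 0.42), beyond the highest such runs in most permuted orders (permutation p = 0.0012, and 0.0148 and 0.0019 for runs of 9 and 17). For the segment 1 hubs in or beside these runs (F31, R33, F38 and R44), a raised region and fragment efficiency both stay open. R81 and R83 lie outside the runs. Their neighbours F80, F82 and F84 had effects of 0.018, 0.0074 and -0.17, against 1.30 for R81 and 0.60 for R83. These values give no sign of a raised region in the fragments that touch R81 and R83. Effects farther out were mixed. On the low side they were -0.64 for R79, 0.52 for F78, -0.26 for R77, -0.34 for F76 and 0.83 for R75. On the high side they were -0.23 for R85 and -0.89 for F86. For all hubs, a true hub no wider than a single fragment stays open.

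The 25 strongest interactions were repeated in both libraries with at least 9.58 times the expected count, so counting noise is not their source. In all, 153 pairs were called, against at most 16 in permutations and 21 in simulated counts with independent noise and no raised pair. Noise may therefore account for some of the 153. Whether each called pair is a product of a single primer pair bears on its reading as a contact. Primers that resemble each other could give such products, which was not tested. Pairs of neighbouring fragments that share neither primer had a mean fragment-corrected z of 0.08 around the 153 called pairs. Around random pairs at the same distance it was 0.02 (one-sided permutation p = 0.0015). The random pairs were drawn as independent, while 110 of the 153 called pairs involve the 13 hubs, so many of their neighbours share fragments. This p may therefore be too small, and the test does not decide whether such products are the source of all of them. Around the 25 strongest the mean was 0.02 against 0.006 by chance (permutation p = 0.3641). The pairs themselves averaged 1.55, but only 8 of them reached 2 in both libraries. This test therefore bears little on those of the other 17 with values near 0. Around the 18 called with additive fragment effects removed the mean was 0.04 (permutation p = 0.0788), while these pairs averaged 2.54. A product of that primer pair alone, or a contact narrower than the spacing of the fragments, could account for those 8, including F517-R41 and F165-R819. It is not excluded for those 18. The other 17 had lower fragment-corrected z, such as 1.95 and 1.77 for F115-R70 and 0.16 and 0.20 for F346-R33. Values near 0, as for F346-R33, leave little that is particular to the pair, so neither explanation covers all 25. Higher ones, as for F115-R70 and for F34-R181 (1.90 and 1.91), still hold a part particular to the pair. For such pairs both explanations stay open.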
